A study of Saccharomyces cerevisiae with 262 samples.

How the data were processed

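Transcript levels were measured on 2-colour arrays in 262 hybridisations of RNA from BY4716, from RM11-1a and from haploid segregants of their cross, each against a reference pool of BY4716 RNA. The deposited values are log2 ratios of reference over own RNA, which the authors had centred to a mean of 0 on each array: the largest absolute array mean was 1.16e-08. The scanner, background correction and spot filters are not given in the sources used here. The base and the direction of the ratio were not stated there either. Values reach 11.98 in absolute size and 3 exceed 11.09, the natural logarithm of a 16-bit range, so base 2 was taken. Arrays of both dye orientations run the same way, and LEU2, URA3, HO, LYS2 and the mating-type genes set the direction. The sign was turned so that all values are own RNA over reference. Array medians lay between −0.0735 and 0.0969 as deposited, with group medians of −0.013 in BY, −0.0357 in RM and −0.00185 in segregants. The label description calls every sample a segregant, and the groups were taken from the source names and titles.

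Of 7085 probes, 5645 carried 1 gene symbol, all found in the reference gene table, 1440 carried none and are not named, and 180 had no value on any array. For 40 genes with more than 1 probe, a single probe stood for the gene in lists. The value of a dye-swap pair was the mean of its 2 arrays and was missing where either lacked the probe. RM pairs that repeat a replicate number were averaged first, so that RM counted 6 replicates, because the labels do not say whether the repeats are new cultures. Nor do they say whether replicates of a parent are separate cultures, so p-values measure only the spread between these samples. No date or batch is given for the parents.

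The parents were compared with limma (version 3.58.1 in R 4.3.3) by lmFit and eBayes on BY and RM alone, for probes with at most 1 missing replicate per parent and a value in at least 80% of segregants, with Benjamini-Hochberg adjusted p under 0.05. The segregant mean was compared with the parental midpoint by the same functions on all 3 groups. Variability was tested by limma on absolute deviations from the group mean, scaled for group size, between segregants and both parents, with the first array repeat of each RM number so that every value is a single pair. Broad-sense heritability was taken as 1 minus the pooled within-parent variance over the segregant variance, and negative estimates were kept. Segregants were counted as transgressive over 2 pooled parental SD outside the parental means, and the threshold was the smallest count at which 100 regroupings gave at most 5% of the observed number of probes. A mixture of 2 Gaussians of equal variance was called over 1 Gaussian (mclust 6.1.1) at a BIC difference over 10 with at least 20% of segregants in each component.

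The text uses 22 gene lists, written before the data were examined. So were the rule for named genes and the tests, apart from those named below as chosen after the results were seen. Lists with at least 3 tested members, other than the strain markers, were tested with limma camera, with a preset correlation of 0.01 and with an estimated one; for camera 2.89% of the parental values and 2.88% of the midpoint values were missing and filled with group means. List coherence was the mean pairwise r over segregants against 10000 random lists matched on segregant variance in 10 bins. Of 8 pairs of lists fixed in advance, 6 were correlated with 100000 permutations, and a pair with separate clusters on either list was left out. Marker shares have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Scripts also used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

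Named genes are the strain markers; between the parents the 10 highest and 10 lowest called genes whose replicates do not overlap, and up to 4 members per list with the lowest adjusted p; at the midpoint the 8 highest and 8 lowest called genes; for variance the 15 highest heritability estimates among called genes and up to 3 members per list; the 10 genes with the most transgressive segregants; and the 15 bimodal genes with the highest BIC difference. Probes without a gene name are not named.

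The steps were tested on simulated data of the same size. The parental test recovered 93% of changes of 0.5 and 97% of changes of 1 log2 unit, with 5% of calls unchanged probes, and the midpoint test 95% and 97%. The absolute-deviation test recovered 0 of 100 probes at 2 times and 0 of 100 at 3 times the parental SD when 200 of 2615 probes were changed, 94.5% at 5 times, and 90.2% at 3 times when 1000 were changed; with 200 changed the F ratio recovered 82% at 3 times and 100% at 5 times, and with 1000 changed 97.4% at 3 times. The transgressive count recovered 18% at 2 and 70% at 3 times the SD. The mixture recovered 16% of modes 3 SD apart and 99% of modes 4 SD apart, and camera found the 1 shifted list and 0 of 18 others. Simulated probes were independent of each other. In the parental data the estimated correlation within a list was 0.82 for respiration and 0.85 for stress response. The simulation therefore does not show how often camera with the preset correlation calls an unshifted list in these data.

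Alternatives were median-centred arrays, quantile normalization between pairs, each dye orientation alone, looser filters, other uses of the RM repeats, a block on replicate number, array weights, other variance tests and limits, and each parental replicate left out in turn. Sets with BY replicates 3 to 6 alone, with the sign of BY replicates 1 and 2 turned, and without segregants 21-1-d, 22-5-d and 23-2-d were added after the data were seen.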

Results

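The series measured transcript levels on 262 spotted 2-colour arrays of budding yeast, in a cross between the laboratory strain BY4716 (BY) and the vineyard isolate RM11-1a (RM). Every array compared RNA of a haploid strain with a reference pool of BY4716 RNA, and the arrays formed 131 dye-swap pairs, in which the strain's own RNA carried Cy5 on the first array and Cy3 on the other. BY gave 6 pairs, RM gave 12 pairs under 6 replicate numbers, and 113 haploid segregants of the cross gave 1 pair each. The arrays carried 7085 probes, of which 5645 had a gene name, and 3597 to 6581 probes were measured on an array, with a median of 4756 on BY arrays, 6488 on RM arrays and 6341 on segregant arrays. The 2 arrays of a pair correlated across probes with a median r of 0.870 in RM, 0.732 in segregants and 0.383 in BY, where the pairs were self-comparisons with little signal, and probes are not independent replicates. The standard deviation (SD) across probes had a median over pairs of 0.216 in BY, 0.593 in RM and 0.440 in segregants. The precision of each value is limited by the number of arrays.

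All values below are log2 ratios of own RNA over the reference pool. This direction is likely rather than stated: it was set by LEU2 and URA3, which are deleted in RM11-1a derivatives, by LYS2, which is deleted in BY4716, and by HO and the mating-type genes, so the direction of these genes is not independent evidence. Were the ratio inverted, every "higher" and "lower" below would change places. The base of the logarithm was likewise taken from the range of the values.

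The comparison of the parents asked which transcripts differ between the laboratory and the vineyard strain. Most tested genes of respiration, of the mitochondrial ribosome, of ergosterol synthesis and of amino acid synthesis were called higher in RM than in BY, and most of those of daughter-cell separation, of alpha mating type and of glycolysis lower, with the counts and tests of each list below. Genes were ranked among the called genes with a name whose RM and BY replicates did not overlap. The highest was URA1, which encodes dihydroorotate dehydrogenase of pyrimidine synthesis, at 2.74 log2 units above BY in 6 of 6 replicates (SE 0.0794, n = 6 and 6, limma adjusted p = 5.2e-12). It was followed by OAC1, a mitochondrial carrier (2.42, SE 0.0889), MSC1 (2.42, SE 0.409), CYT1, cytochrome c1 (2.35, SE 0.223), BAT1, a branched-chain aminotransferase (2.20, SE 0.0543), RIP1, the Rieske protein of the respiratory chain (2.19, SE 0.169), HSP12 (2.17, SE 0.296), SDH1 (2.16, SE 0.24), COX5A (2.04, SE 0.115) and AGA2, a subunit of a-agglutinin (1.98, SE 0.206). The lowest were the asparaginase genes ASP3-3 (−7.88, SE 0.48), ASP3-2 (−6.87) and ASP3-1 (−6.65), the Ty element genes YBL005W-A (−6.70), YMR046C (−6.58), YBR012W-B (−6.16) and YDR170W-A (−5.75), and the single genes LEU2 (−5.96, SE 0.16), STE3, the receptor for a-factor (−5.89), and SAG1, alpha-agglutinin (−5.61). The lack of overlap in these 20 genes was a condition of their choice and is not separate evidence. The ASP3 and Ty genes exist in near-identical copies, so a probe may have read several copies. LEU2 is deleted in RM11-1a derivatives, and signal over background was not used. The sizes and order of these lowest differences may therefore depend on the background in RM.

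Of 2639 probes tested, for 2423 named genes, 1478 (56.0%) differed between the parents at an adjusted p under 0.05 in limma, 919 higher and 559 lower in RM. Among these, the median absolute difference was 0.32, and 86 were higher and 88 lower by over 1 log2 unit. The replicates did not overlap for 1014 of the called probes. These were called on the same values, so the lack of overlap is not separate evidence. For probes not chosen in this way, with 6 values on each side, chance gives a share of 0.216%. Settings that moved the count of 1478 by over 1.5 times were a fit with all 3 groups, which called 474 and ended the calls of 37 of 85 named genes at unchanged differences (among them HSP12, AGA2, MF(ALPHA)1, MF(ALPHA)2, LEU4, BAP2, HIS5, HOM2, YHB1, HXK2, PGI1, PGK1 and PFK1), a value on 1 of the 2 arrays of a pair, which called 2639 of 5067, and a filter of at least 3 values per group, which called 2414 of 4515.

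All 27 tested genes of respiration, which encode respiratory complexes, ATP synthase and enzymes of the tricarboxylic acid cycle, were called higher in RM, with a median difference of 1.27. COX5A was followed in the strength of its call by COX6 (1.27, SE 0.0829), QCR2 (1.82, SE 0.136) and QCR8 (1.34, SE 0.101). The list was called by limma camera with a preset correlation (adjusted p = 5.471e-09) but not with an estimated one (adjusted p = 0.343). The mean over these genes was 0.11 in BY replicates 1 and 2, −0.50 in BY replicates 3 to 6, and 0.95 in RM, whose replicates lay between 0.82 and 1.13. Of 22 mitochondrial ribosomal protein genes, 20 were higher and 2 did not pass the test, with a median difference of 0.39; MRPL38 (0.80, SE 0.058), MRPS9 (0.60, SE 0.0445), MRPS16 (0.53, SE 0.0336) and MRPL23 (0.48, SE 0.0381) had the strongest calls. The adjusted p was 2.757e-06 with the preset correlation and adjusted p = 0.259 with an estimated correlation.

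Of 22 ergosterol synthesis genes, 18 were higher and 1 lower in RM, with a median difference of 0.47. ERG9, squalene synthase (0.95, SE 0.039), ERG20, farnesyl diphosphate synthase (0.86, SE 0.046), ERG26 (0.69, SE 0.0396) and ERG10 (0.58, SE 0.0317) had the strongest calls, and the list had an adjusted p of 9.189e-06, with adjusted p = 0.272 with an estimated correlation. Of 22 genes of general amino acid synthesis, 16 were higher, 2 lower and 4 not called, with a median difference of 0.44 and an adjusted p of 0.0157, with adjusted p = 0.343 with an estimated correlation. HIS5 (0.89, SE 0.0626), SER3 (0.85, SE 0.0586), SER33 (0.57, SE 0.0383) and HOM2 (0.52, SE 0.0357) led this list, whose mean was 0.03 in BY replicates 1 and 2, −0.51 in BY replicates 3 to 6 and 0.19 in RM. Of 12 genes of leucine and branched-chain amino acid metabolism, 8 were higher and 3 lower, with a median difference of 0.70 and an adjusted p of 0.0417, with adjusted p = 0.299 with an estimated correlation. OAC1 and BAT1 were joined there by LEU4 (1.24, SE 0.0665) and the permease gene BAP2 (0.63, SE 0.0356).

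Of 9 genes of daughter-cell separation, whose products digest or remodel the wall between mother and daughter, 8 were lower and 1 higher in RM, with a median difference of −1.54. DSE2 differed by −5.49 (SE 0.0835), SUN4 by −2.37 (SE 0.0555), DSE4 by −1.55 (SE 0.045) and PRY3 by −1.54 (SE 0.0456). This list had an adjusted p of 2.623e-07 with the preset correlation and was the only one still called with an estimated correlation, at an adjusted p of 0.00333. All 6 alpha-specific genes were lower, with a median of −3.29. AFB1 differed by −3.41 (SE 0.0763), MF(ALPHA)1 by −3.17 (SE 0.181) and MF(ALPHA)2 by −1.26 (SE 0.0928), next to STE3 and SAG1, and the adjusted p was 2.215e-06, with adjusted p = 0.104 with an estimated correlation. AGA2 was the only a-specific gene among the tested probes. Of 6 glycolysis genes, 5 were lower, with a median of −0.29, an adjusted p of 0.00156 and adjusted p = 0.158 with an estimated correlation. HXK2, a hexokinase, differed by −0.89 (SE 0.049), PGI1 by −0.46 (SE 0.0453), PGK1 by −0.30 (SE 0.0429) and PFK1 by −0.27 (SE 0.0324).

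The other 11 of 19 lists were not called with either correlation. Of the stress response genes 9 were higher, 3 lower and 6 not called (adjusted p = 0.613), with HSP104 at −0.81 (SE 0.095), HSP26 at −2.57 (SE 0.343) and TPS1 at 0.88 (SE 0.136). The mean of this list was 0.41 in BY replicates 1 and 2, −0.60 in BY replicates 3 to 6 and 0.01 in RM, whose replicates lay between −0.15 and 0.41. Of 16 cytosolic ribosomal protein genes 3 were lower, RPS13 (−0.32), RPL25 (−0.22) and RPL3 (−0.16), and 13 were not called (adjusted p = 0.0793); the means were −0.11 in BY replicates 1 and 2, 0.24 in BY replicates 3 to 6 and 0.02 in RM. Of 22 ribosome biogenesis genes TIF6 was higher (0.21) and RPA135 (−0.29) and HAS1 (−0.32) lower (adjusted p = 0.273), with means of −0.36, 0.21 and −0.06 in the same 3 sets of replicates. Among 8 genes of heme and oxygen regulation, 6 were higher and 2 lower (adjusted p = 0.201), among them ANB1 at 1.27 (SE 0.0753), YHB1, a flavohemoglobin, at 1.60 (SE 0.109) and HAP1, the heme-dependent activator, at −1.70 (SE 0.0414). Of 7 pyrimidine genes 4 were higher and none lower (adjusted p = 0.0793), with URA4 at 1.31 (SE 0.0626), URA2 at 0.98 (SE 0.0585) and URA5 at 0.22 (SE 0.0796) beside URA1. Pheromone response had 2 higher and 3 lower of 7 (adjusted p = 0.298), with AGA1 at −2.33 (SE 0.0637) and SST2 at −1.13 (SE 0.0722). Sulfur amino acid genes had 4 higher and 1 lower of 8 (adjusted p = 0.273), with MET22 at 0.88 (SE 0.0554). Iron genes had 1 higher and 3 lower of 5 (adjusted p = 0.273), with FET3, the multicopper oxidase of iron uptake, at −1.57 (SE 0.129). Phosphate genes had 3 higher and 2 lower of 5 (adjusted p = 0.613), zinc genes 1 and 1 of 8 (adjusted p = 0.497) and lysine genes 1 and 1 of 4 (adjusted p = 0.77). For the lysine list the median was 0.03 while the mean, at −0.01, and the test pointed down. No flocculation gene was among the tested probes.

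Counts adjusted over the list alone were equal to those over all probes except for general amino acid synthesis (17 higher), stress response (10 higher), iron (2 higher), cytosolic ribosome (1 lower) and ribosome biogenesis (0). Whether the number of called lists is above chance was not settled: 26 of 100 splits of the 12 parental replicates called at least 8 lists, up to 10. The median over the splits other than the real one was 6 lists. Splits that mix the strains unevenly still hold part of the difference between RM and BY. BY replicates 1 and 2 stood apart from BY replicates 3 to 6, with a mean r of −0.374 between the sets, and with BY replicates 3 to 6 alone 11 lists were called, adding cytosolic ribosome (median −0.21, adjusted p = 0.00173), ribosome biogenesis (−0.29, adjusted p = 0.00116) and stress response (0.70, adjusted p = 0.0299). That refit kept all RM replicates, although RM replicate 1 was also high in stress response (0.41) and low in ribosome biogenesis (−0.29). Quantile normalization between pairs ended the calls of 11 of 85 named genes, among them HSP26 (from −2.57 to −1.08), YHB1 (from 1.60 to 0.59), URA5, RPL3, RPA135, TIF6 and HAS1. Over 14 alternatives, each leave-one-out fit aside, the call of RPL3 ended in 9, TIF6 in 5, URA5 and LYS9 in 4 each, and RPL25, HAS1, LYS5 and ARN1 in 3 each, where LYS9 and LYS5 are the called genes of the lysine list. All 12 RM pairs as replicates added the pyrimidine list (adjusted p = 0.0497).

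**Figure D1:**
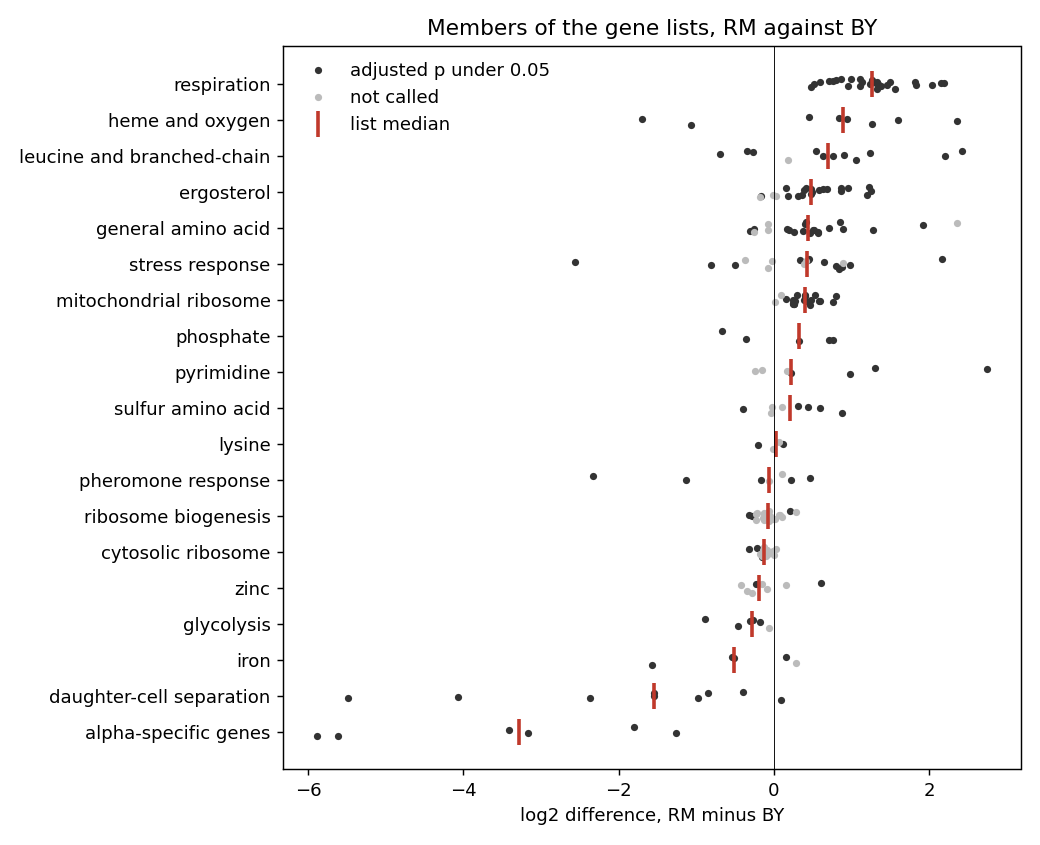
Each point is a tested gene of the named list, placed by its log2 difference between RM and BY on the horizontal axis; dark points have an adjusted p under 0.05, grey points do not, and the red bar is the list median. Respiration has its 27 genes above 0 and a median of 1.27, and the alpha-specific genes their 6 below 0 and a median of −3.29.

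For the deleted and mating-type genes, segregants were counted by the parental mean that they lay nearer. This count reads transcript levels and is not a direct measure of inheritance. LEU2 lay nearer the BY mean than the RM mean in 55 of 113 segregants (48.7%, exact binomial 95% interval 39.2 to 58.3%), URA3 in 52 of 113 (46.0%, 36.6 to 55.6%), HO, the mating-type switching endonuclease, in 53 of 113 (46.9%, 37.5 to 56.5%) and LYS2 in 59 of 107 (55.1%, 45.2 to 64.8%). Among alpha-specific genes, STE3 was nearer BY in 61 of 113 (54.0%, 44.4 to 63.4%), SAG1 in 49 of 113 (43.4%, 34.1 to 53.0%) and AFB1 in 58 of 113 (51.3%, 41.7 to 60.8%). Among a-specific genes, STE2, the receptor for alpha-factor, averaged 5.13 in RM and was nearer BY in 57 of 112 (50.9%, 41.3 to 60.5%), BAR1 in 56 of 110 (50.9%) and STE6 in 55 of 112 (49.1%). These counts took a value from either array of a pair. LYS2 was measured in 1 BY pair, BAR1, MFA1 and MFA2 in 2 and STE6 in 3, and no BY pair had BAR1 or STE6 on both arrays, so their BY means are less certain. The intervals of MF(ALPHA)2 (31.9%, 23.4 to 41.3%), MFA1 (28.6%, 20.4 to 37.9%) and ASG7 (37.8%, 28.8 to 47.5%) lay below 50%, and those of the other 14 markers included it. For these 3 genes segregants went far beyond the RM mean: to −6.08 against −1.24 for MF(ALPHA)2, 4.62 against 0.52 for MFA1 and 2.43 against 0.23 for ASG7. All alpha-specific and a-specific genes follow mating type, so these low shares are not read as unequal inheritance.

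**Figure D2:**
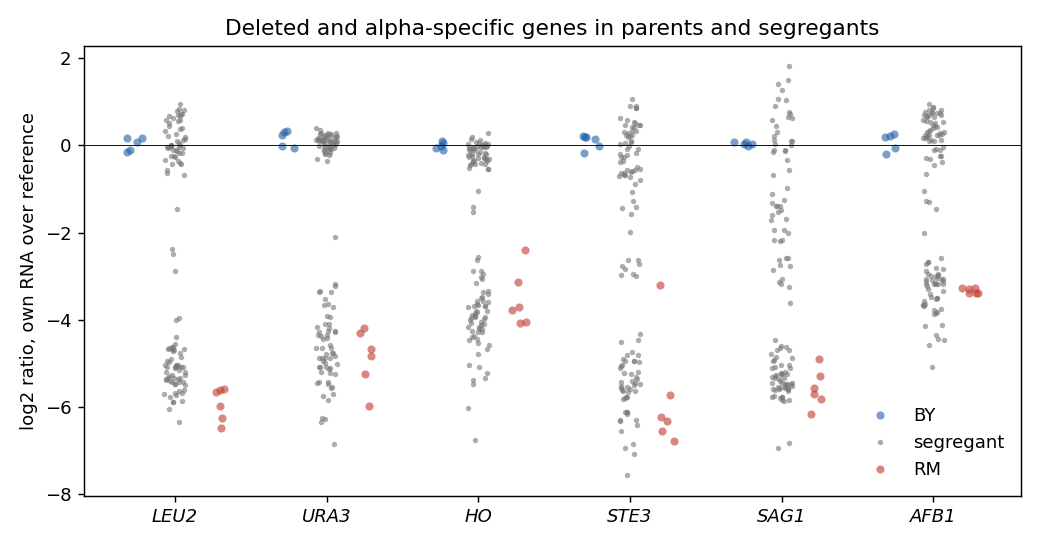
Each point is a strain's log2 ratio of own RNA over reference for LEU2, URA3, HO, STE3, SAG1 and AFB1, in BY replicates (blue), segregants (grey) and RM replicates (red). Segregants form a set near BY and a set near RM for LEU2, URA3 and HO, and SAG1 values also fall between the parents.

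The midpoint comparison asked where the mean of the segregants departed from the mean of the 2 parents on the log2 scale. That mean is what inheritance additive on this scale, without interaction, would give. Ty element genes stood furthest above the midpoint. YMR046C was 2.63 log2 units above it (SE 0.227, limma adjusted p = 7.75e-18), with a segregant mean of −0.82 (SD 0.749) between −0.17 in BY and −6.75 in RM. YBL005W-A was 2.59 above (SE 0.239), YBR012W-B 2.23 (SE 0.212), YDR170W-A 2.11 (SE 0.209), YMR045C 1.46 (SE 0.221) and YBL005W-B 1.40 (SE 0.216). These elements lie at many sites of the BY genome and their copies share sequence, so that a probe may read copies from several sites. Copies that add on the unlogged scale would give a segregant mean above the log2 midpoint, so these departures need not mean inheritance that is not additive. RM values as low as −6.75 may also lie near background, which was not checked, so the sizes and order of these departures are uncertain. The hexose transporter gene HXT13, of a family of near-identical genes, was 1.30 above (SE 0.196) and YMR158C-A 0.75 above (SE 0.19).

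The lowest were smaller. HSL1, a kinase of the morphogenesis checkpoint, averaged −0.13 in segregants against 0.07 in BY and 0.44 in RM, a difference of −0.38 from the midpoint (SE 0.0868, limma adjusted p = 0.00444). BDF1, a bromodomain protein (−0.24, SE 0.0612), the septin gene CDC3 (−0.20, SE 0.0602), AIM9 (−0.20, SE 0.0511), EPL1 of a histone acetyltransferase complex (−0.19, SE 0.0546), NDD1, an activator of mitotic genes (−0.18, SE 0.0488), YEL023C (−0.18, SE 0.0461) and RSC4 of a chromatin remodelling complex (−0.18, SE 0.0471) followed. In all, 58 of 2639 probes were called by limma, 41 above and 17 below, with a median SE of 0.0764 over all tested probes. This split depended on the setting: it was 54 above and 8 below with median-centred arrays, 41 and 3 with the Cy5 arrays alone, 33 and 23 with the Cy3 arrays alone, 331 and 372 with array weights by group, and from 8 to 13 were below when single parental replicates were left out (8 without BY replicate 5). Of the called probes 18 departed by over 0.5 log2 units and 27 had a segregant mean outside both parental means.

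No list member was called over all probes, and 0 of 19 lists were called by limma camera with either correlation. Leucine and branched-chain metabolism, general amino acid synthesis and respiration had an unadjusted p under 0.05 with the preset correlation, 3 lists whose adjusted p was 0.156. Adjusted over the list alone, 1 gene each passed in daughter-cell separation, leucine and branched-chain metabolism and general amino acid synthesis, all above the midpoint. Median, mean and test differed in sign for pheromone response, pyrimidine, ergosterol, cytosolic ribosome and zinc, whose medians were −0.08, −0.01, 0.0014, −0.0033 and 0.01.

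The midpoint count rested on the fit. It was 703 with array weights by group, 107 with quantile normalization, 102 with a value on 1 of the 2 arrays, 100 with all 12 RM pairs as replicates, 38 with the first RM array repeat, 37 without BY replicate 5 and 32 with BY replicates 3 to 6 alone. With quantile normalization YMR045C, YBL005W-B, HXT13, YMR158C-A, EPL1 and NDD1 were no longer called, and with BY replicates 3 to 6 alone BDF1, CDC3, EPL1, YEL023C and RSC4 were not. The Cy5 arrays alone ended the calls of BDF1, CDC3, AIM9, EPL1, NDD1 and RSC4, the Cy3 arrays alone those of EPL1, NDD1 and YEL023C, and median-centred arrays those of CDC3 and EPL1. The first RM array repeat ended those of CDC3, EPL1, NDD1 and YEL023C. Of the 8 lowest genes, HSL1 alone was called in all 11 alternatives, each leave-one-out fit aside.

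Variation among segregants was compared with the spread between pairs within the parents, to estimate the share of the variation in a transcript that is inherited. If the parental replicates were repeats of 1 culture, the variation between cultures would count as inherited and the estimates would be too high. The branched-chain permease gene BAP2 and DSE4, a daughter-cell glucanase, each had a broad-sense heritability estimate of 0.994: the SD was 0.737 among segregants and 0.0572 within parents for BAP2, and 0.799 and 0.0626 for DSE4. AFB1 (0.992), the transcription factor gene PHD1 (0.992), ADE17 of purine synthesis (0.991), PRY3 (0.990), MET16 (0.989), the meiotic regulator IME1 (0.989), PRM7, ARO8, CBS2, GCV2 and ACS2 (0.988 each), SHM2 and CIT2 (0.987 each) completed the 15 highest among called probes. The median estimate over 2615 probes was 0.801, with quartiles of 0.669 and 0.899. It was over 0.9 for 645 probes and negative for 1.72%. The median SD was 0.259 among segregants and 0.110 within parents.

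Of the 2615 probes, 1106 (42.3%) were called more variable among segregants and 2 less variable by limma on absolute deviations. Of the variable probes, 791 also differed between the parents and 315 were not called there, and for 542 the 95% interval of the parental difference lay within 1.25-fold. A further 677 probes differed between the parents and were not called variable, and 832 were neither.

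The share of each list called variable was counted, and differences between lists were not tested. All 6 alpha-specific and all 6 glycolysis genes were called, as were AGA2, 21 of 22 mitochondrial ribosomal protein genes, 11 of 12 genes of leucine and branched-chain metabolism, 8 of 9 of daughter-cell separation, 7 of 8 of sulfur amino acids, 17 of 22 of ergosterol synthesis, 16 of 22 of general amino acid synthesis, 6 of 8 of heme and oxygen, 5 of 7 of pheromone response and 3 of 4 of lysine. The counts were 8 of 18 for stress response, 4 of 8 for zinc, 3 of 7 for pyrimidine, 2 of 5 for phosphate, 2 of 5 for iron, 2 of 27 for respiration (IDH1 and COX5A), 1 of 16 for cytosolic ribosome (RPL39) and 0 of 22 for ribosome biogenesis. Adjusted over the list alone the count was 22 for mitochondrial ribosome, 18 for ergosterol, 18 for general amino acid, 10 for stress response, 7 for pheromone response, 3 for iron, and 0 for respiration, cytosolic ribosome and ribosome biogenesis, and equal for the others. Median heritability was 0.909 for mitochondrial ribosome, 0.923 for ergosterol and 0.964 for glycolysis, and 0.564 for respiration and 0.489 for ribosome biogenesis. In the last pair of lists BY replicates 1 and 2 stood apart from BY replicates 3 to 6, as given above, and that distance is part of the parental spread; with BY replicates 3 to 6 alone the estimate for COX5A went from 0.798 to 0.956, and of the named genes RPS15 and RPS3 of the cytosolic ribosome and RPA135 of ribosome biogenesis were then called.

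The count depended on the test. Limma on squared deviations called 28 probes and an F ratio of the variances 1712, of which 1093 were shared. Quantile normalization gave 401 probes and a median heritability of 0.536, and turned the estimate for RPL39 from 0.894 to −1.08. In simulated data the test on absolute deviations recovered none of 200 probes with 3 times the SD when the other probes did not change, so a probe that was not called may still vary.

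**Figure D3:**
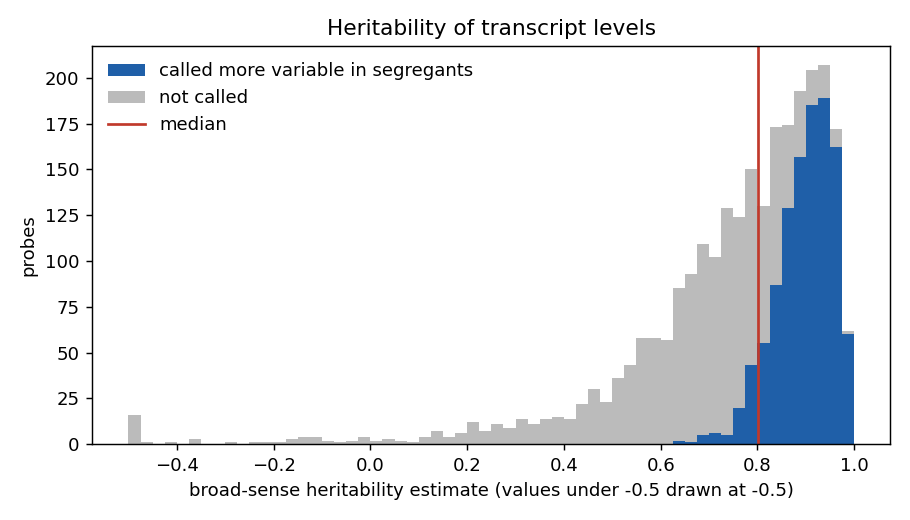
Histogram of the broad-sense heritability estimate over 2615 probes, with the number of probes on the vertical axis; probes called more variable among segregants are blue, the others grey, and estimates under −0.5 are drawn at −0.5. The red line marks the median of 0.801.

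Transgressive segregation, in which segregants exceed both parents, was counted as segregants lying over 2 parental SD outside the range of the parental means. The purine synthesis gene ADE17 had 97 such segregants, 37 above and 60 below, with parental means of −0.06 in BY and 0.02 in RM that were not called different (limma adjusted p = 0.14). It was followed by the chaperone gene CAJ1 (86, with 12 above and 74 below), BEM3 (86, with 18 and 68), BGL2, a cell wall glucanase (85, with 68 and 17), RSC4 (83, with 2 and 81), TOM70 (83, with 24 and 59), RPN8 of the proteasome (83, with 11 and 72), ADE3 (82, with 55 and 27), PCM1 (80, with 61 and 19) and SAM3, a permease (80, with 34 and 46). A threshold of 30 segregants was passed by 801 of 2615 probes (30.6%), against a mean of 37.2 probes in 100 regroupings of the labels, which set this threshold. In these regroupings segregants stood among the parents, so the contrast does not separate transgression from the wider spread of segregants. Of the 801 probes, 693 had at least 5 segregants on each side, and 458 were not called between the parents while 343 were.

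By list, transgressive calls were made for 13 of 22 genes of general amino acid synthesis, 9 of 22 of mitochondrial ribosome, 7 of 12 of leucine and branched-chain metabolism, 5 of 7 of pheromone response, 4 each of daughter-cell separation, sulfur amino acids, ergosterol and glycolysis, 3 each of lysine and alpha-specific genes, 2 each of heme, cytosolic ribosome and zinc, 1 each of ribosome biogenesis, stress response and phosphate, and 0 of 27 for respiration, 0 of 7 for pyrimidine and 0 of 5 for iron. Quantile normalization gave 179 transgressive probes, with a threshold of 40 segregants in place of 30, and all 12 RM pairs as replicates 1270, with a threshold of 20.

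A distribution with 2 modes was called for 152 of 5523 probes by a Gaussian mixture, with a median of 34.9% of segregants in the smaller component. LEU2 had the highest difference in the Bayesian information criterion (BIC), 167, with modes at −5.13 and 0.03 and 47.8% of segregants in the smaller one. It was followed by ASP3-3 (modes at −6.58 and 0.27), ASP3-1, the sodium pump gene ENA2 (−2.34 and 0.22), URA3 (−4.72 and 0.03), ASP3-2, SCW11 (−3.62 and −0.04), BRE4 (0.06 and 1.17), the daughter-specific gene DSE1 (−4.07 and −0.04), STE6 (−0.18 and 2.86), AFB1 (−3.37 and 0.22), STE2 (0.00 and 4.65), ENA5 (−2.67 and 0.22), HO (−4.04 and −0.23) and ASP3-4. The ASP3 and ENA genes are families of similar copies. Of the 152 probes, 80 were in the parental test and 71 of these differed between the parents. The distance between the modes was within 25% of the parental difference for 39 of the 80, with a rank correlation of 0.666 across probes, which are not independent replicates. A BIC difference over 20 in place of 10 gave 95 probes, and components of at least 10% in place of 20% gave 260.

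Members of most lists varied together among the 113 segregants. The mean pairwise r was 0.836 for alpha-specific genes, 0.744 for cytosolic ribosome, 0.701 for ribosome biogenesis, 0.658 for mitochondrial ribosome, 0.650 for general amino acid synthesis, 0.645 for lysine, 0.626 for daughter-cell separation, 0.604 for stress response, 0.599 for respiration, 0.592 for leucine and branched-chain metabolism, 0.446 for ergosterol, 0.441 for phosphate, 0.415 for pheromone response, 0.399 for sulfur amino acids and 0.388 for glycolysis, each above all 10000 random lists matched for variance. It was 0.569 for a-specific genes, 0.279 for iron, 0.123 for pyrimidine, 0.148 for zinc and 0.338 for flocculation, above 99.97%, 99.98%, 99.72%, 97.59% and 97.41% of random lists. The list of heme and oxygen did not vary together (0.0048, above 21.11%). These are values across genes, which are not replicates.

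The mean values of 6 pairs of lists were correlated across the 113 segregants with two-sided tests of 100000 permutations. Cytosolic ribosome correlated positively with ribosome biogenesis (r = 0.811, rho = 0.762) and negatively with stress response (r = −0.505, rho = −0.580). Respiration correlated positively with stress response (r = 0.553, rho = 0.522) and with mitochondrial ribosome (r = 0.406, rho = 0.393), as did ergosterol with heme and oxygen (r = 0.459, rho = 0.503), although the members of the last list did not vary together. For these 5 pairs the permutation p of r was 1e-05, the smallest that the permutations can give, and 1.2e-05 after adjustment over 6 pairs; for rho it was at most 2e-05, and 2.4e-05 after adjustment. Each r was taken again without the 2 segregants farthest from the median of a single list of the pair. That list was cytosolic ribosome for its 2 pairs, then stress response, mitochondrial ribosome and ergosterol. It was then 0.781, −0.520, 0.514, 0.399 and 0.470 for r in the same order. Centred within the first number of the segregant names, the only batch-like label, r was 0.779, −0.505, 0.62, 0.307 and 0.486. Cytosolic and mitochondrial ribosome had r = 0.184 (permutation p = 0.0507, adjusted 0.0507) and rho = 0.108 (permutation p = 0.254, adjusted 0.254), with 0.0952 without 2 segregants and 0.0757 within the first number, and passed the threshold in the Cy5 arrays alone (r = 0.240, adjusted p = 0.0108). Leucine with general amino acid synthesis and daughter-cell separation with pheromone response were not correlated, because the segregants fell into separate clusters on a list of each pair.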

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

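In this part the refits with BY replicates 3 to 6 alone, with the sign of BY replicates 1 and 2 turned, and without 3 segregants, and the regroupings that set the transgressive threshold anew, were chosen only after the results were seen, and so were the single genes outside the parental test that are named.

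BY replicates 1 and 2 opposed BY replicates 3 to 6: the pair values correlated with r = 0.750 between BY 1 and BY 2 and with a mean of 0.869 among BY 3 to 6, but with a mean of −0.374 between the sets (−0.448 to −0.284). In list means looked at afterwards, RM replicates 1 and 2 lay to the same side of RM 3 to 6 for several lists. Among them were stress response (0.41 and 0.09 against −0.15 to −0.0037), ribosome biogenesis (−0.29 and −0.07 against −0.05 to 0.04) and respiration (1.13 and 1.05 against 0.82 to 0.93). The same held for cytosolic ribosome (−0.12 and 0.01 against 0.02 to 0.10) and pyrimidine (0.66 and 0.75 against 0.79 to 0.82). It also held for heme and oxygen, lysine and pheromone response. It did not for general amino acid synthesis, zinc, leucine and branched-chain metabolism, sulfur amino acids, ergosterol, mitochondrial ribosome and alpha-specific genes, where the 2 sets of BY replicates also lay apart. A shift shared by replicate number was examined only by the correlations and the block on that number given below. Arrays deposited with the whole ratio negated are argued against, since 4 of 4 arrays of BY 1 and BY 2 kept the sign of their dye label in the gene-specific dye profile. Own and reference RNA exchanged between the dyes on both arrays of a pair would keep that sign, so the profile cannot decide on it. Dye effects of that profile left in the pair means are argued against too, since each pair mean holds both dyes once and removing the profile from each array, at the strength fitted to that array, left the mean r at −0.374. A difference between cultures, RNA preparations or hybridisation days remains open and untested. No biological explanation was tested, since the source names put these replicates in a single group. The sample titles write By for replicates 1 and 2 and BY for replicates 3 to 6, without saying why. With BY replicates 3 to 6 alone 1809 probes differed between the parents, and 1817 with the sign of BY 1 and 2 turned, against 1478.

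Same-dye arrays gave 29 pairs correlated below −0.3 across probes, each holding an array of BY replicates 3 to 6 and a segregant. Their direction was kept.

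The arrays of segregants 22-5-d and 23-2-d did not match within a pair, with r of 0.156 and 0.155 between the 2 dyes, where all segregants but these and 21-1-d had at least 0.371. Pairing the Cy5 array of each with the Cy3 array of the other gave r of 0.798 and 0.796. Labels of 1 array of each strain crossed would make marker genes match across the strains, and 10 of 11 comparisons at LEU2, URA3, LYS2, HO, SAG1 and STE3 lay within 1.5 log2 units when crossed, against 2 of 11 as labelled. A crossed label is therefore a candidate explanation, and which array of each strain carries the wrong name stays open. Segregant 21-1-d had r = 0.0804 with 5 of 6 marker genes in range, and without all 3 strains 56 probes were called at the midpoint, 1108 as variable and 764 as transgressive, against 58, 1106 and 801.

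Splits of the samples tested whether chance gives counts as large. For the parents, 1 of 100 splits of the 12 replicates, the real one, called 1478 probes, the highest other called 20, and 462 splits are possible, so a chance split of these 12 samples can be excluded. The other splits mix RM with BY, which widens their spread. A difference of culture or batch that goes with the strain is not excluded. For the lists, 26 of 100 splits called at least 8, the highest other 10, so chance cannot be excluded. Splits that mix the strains unevenly still hold part of their difference, so this test cannot decide either way. For the midpoint and the variance counts, 1 of 100 regroupings, the real one, reached 58 and 1106, and the highest others were 28 and 7, so chance labels of the pairs can be excluded for both. The midpoint regroupings also mix RM with BY. They therefore do not decide whether segregant means depart from the midpoint. For the transgressive count, with the threshold set anew in each regrouping, 1 of 100, the real one, reached 801, and the highest other was 23, so chance labels of the pairs can be excluded. Regrouping puts segregants among the parents, so the parental spread then holds differences between segregants. The variance and transgressive regroupings therefore show that parental pairs spread less than segregants. They do not tell how many transgressive probes a wider spread alone would give.

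Among 182 groups of parental replicates of named genes, 11 held a replicate far from the others, and chance gives about 5% of groups. SDH1 was 0.47 in BY replicate 1 against −1.06 to −0.78 in the other measured BY replicates. FET3 was −0.37 in BY replicate 1 against 0.35 to 0.51. HOM2 was −0.0050 in BY replicate 2 against −0.11 to −0.08. ANB1 was 0.17 in BY replicate 5 against −0.22 to −0.08. STE3 was −3.20 in RM replicate 6 against −6.78 to −5.72, and ASP3-3 was −10.40 there against −7.72 to −6.85. OAC1 was 2.07 in RM replicate 5 against 2.36 to 2.51, LEU4 was 0.98 there against 1.12 to 1.19, and YBL005W-A was −7.05 there against −6.78 to −6.72. DSE2 was −5.81 in RM replicate 3 against −5.42 to −5.22. SER3 was 0.54 in RM replicate 1 against 0.77 to 0.86.

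Outside the parental test, 20 probes measured in too few BY pairs had a mean over 2 log2 units from 0 in 6 RM replicates, 13 higher and 7 lower. The a-specific genes STE2 (5.13, SD 0.252), BAR1 (4.78, SD 0.257) and STE6 (3.00, SD 0.520) were among the higher, with PHM7 (4.04), the proline permease gene PUT4 (3.66), the catalase gene CTT1 (2.72), MDH2 (2.58) and RTN2 (2.41). SCW11 (−4.15, SD 0.112), a daughter-cell glucanase, ASP3-4 (−4.76), AGP2 (−2.70) and the subtelomeric helicase genes YRF1-4 (−2.23) and YRF1-5 (−2.32) were among the lower.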

How the results depend on the processing

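In this part BY replicates 3 to 6 alone, the turned sign of BY replicates 1 and 2, and the set without 3 segregants were chosen only after the results were seen. Total counts of probes stayed within 1.5 times with median-centred arrays, with each dye orientation alone, with the RM number as a random block (1500 probes between the parents) and without the 3 segregants, in each analysis run with them. The number of called lists was not run with either dye orientation, the random block or the set without 3 segregants, and was 8 again with median-centred arrays. Median-centred arrays moved the share of called probes that were higher in RM from 62.2% to 56.1%, and the probes called below the midpoint from 17 to 8; the Cy5 arrays alone gave 3 there.

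A block on the replicate number that BY and RM share called 1581 probes and 9 lists, adding the cytosolic ribosome (adjusted p = 0.0329 in limma camera), and 1 of 85 named calls, that of RPL3, was not made. The deviations of the same number correlated with r from 0.0948 to 0.435, not over 0.1 in each, and 3 of 6 BY replicates correlated best with the RM replicate of their own number, so that the block was kept as an alternative.

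Quantile normalization, which gives pairs of unequal spread a common one, moved the midpoint count from 58 to 107, the variable count from 1106 to 401, the median heritability from 0.801 to 0.536 and the transgressive count from 801 at a threshold of 30 segregants to 179 at 40, and it reversed the heritability estimate of RPL39 to −1.08. A value on 1 of the 2 arrays called 2639 probes between the parents and 102 at the midpoint, with a heritability of 0.754, and at least 3 values per group called 2414 between the parents; more probes were tested in both. All 12 RM pairs gave 100 at the midpoint and 1270 transgressive probes at a threshold of 20, and the first RM array repeat gave 38. BY replicates 3 to 6 alone gave 32 and a heritability of 0.883. A fit of all 3 groups called 474 between the parents, as its error then holds the spread of segregants. Array weights by group gave 703 at the midpoint. Squared deviations called 28 variable probes and the F ratio 1712. An estimated correlation left 1 of 8 lists. A BIC difference over 20 gave 95 bimodal probes and components of at least 10% gave 260. Apart from the numbers of probes and pairs and the error named here, the cause was not tested.

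Leaving out each parental replicate in turn gave 1377 to 1545 probes between the parents, 37 to 52 at the midpoint, 813 to 1257 variable and 610 to 865 transgressive probes, and a median heritability of 0.79 to 0.83. The lowest midpoint count, 37, was without BY replicate 5. Over all alternatives and named genes, a call was made both as reported and under the alternative 2106 times between the parents, only as reported 104 times and only under the alternative 19 times. These numbers were 312, 54 and 54 at the midpoint, 1313, 126 and 18 for variance, 33, 7 and 5 for lists between the parents, and 25, 0 and 1 for list correlations.

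Signal over background of the spots was not used here, so its limits are not known; fewer probes were measured on BY arrays (median 4756) than on the others, which limits the probes tested. The absolute-deviation test recovered 0 of 200 simulated probes at 3 times the SD when few probes changed, so its count does not bound the number of variable transcripts.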

Other observations

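In this part the test on squared correlations, the test on genes 1 to 4 apart and the description of single lists and genes were chosen only after the result was seen.

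Phosphate genes had a small set of segregants apart from the rest. The mean over the 13 phosphate genes measured in at least 80% of segregants split into 2 components with a BIC difference of 100, the smaller with 6.19% of segregants. VTC1 of the polyphosphate synthase complex had components at 0.13 and 1.94 in 107 segregants, with a BIC difference of 104. Smaller sets also stood apart for lysine (BIC difference 31.8, 16.8% in the smaller component), iron (16.7, 1.77%), sulfur amino acids (15.3, 11.5%) and the cytosolic ribosome (15.2, 7.96%). The scores of daughter-cell separation (BIC difference 118, 44.2% in the smaller component), a-specific genes (102, 48.7%), alpha-specific genes (87.8, 48.7%), pyrimidine synthesis (23.6, 47.8%), general amino acid synthesis (30.4, 20.4%) and leucine and branched-chain metabolism (15.6, 29.2%) split more evenly. The other 11 of 22 lists had a BIC difference under 10.

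A hypothesis was that genes close together on a chromosome vary together among segregants because they are inherited on shared segments. Over 2774 genes, the mean r of genes 5 to 15 genes apart minus that of genes over 100 apart was −0.00121 among segregants (p = 0.693 from 1000 random gene orders) and −2.5e-04 within the parents, and the squared r, tested after this had shown no excess, gave 0.00112 (p = 0.207) and −0.00396, so no excess was found at this distance in either form. Genes 1 to 4 apart, tested last, did show an excess among segregants, of 0.0132 in mean r (central 95% of random orders −0.00629 to 0.00623) and 0.00888 in squared r (−0.00253 to 0.00313). Within the parents it was 0.0044 in mean r (−0.0117 to 0.0119) and −2.952e-04 in squared r, and whether segregants and parents differ was not tested. Inheritance of adjacent genes together may be a cause, but shared promoters and probes that read a neighbouring transcript stay open. The lack of an excess at 5 to 15 genes gives no support to longer segments and does not argue against them. Local effects in opposite directions cancel in the mean r. The mean squared r among segregants was 0.0702 at 5 to 15 genes and 0.0691 over 100 apart, so most of it was not local. Distant pairs lay on the same chromosome too.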
